A study of Homo sapiens
Mus musculus with 4 samples.

How the data were processed

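RNA was measured in 4 subcutaneous tumours grown in NOD/SCID mice from MV4;11, a human acute leukaemia cell line. The labels give 2 untreated tumours and 2 tumours from mice given the curaxin CBL0137, numbered replicate 1 and replicate 2 in each group. Each tumour holds human leukaemia cells and mouse host cells. Per the labels' protocols, RNA was isolated with Trizol and libraries came from a stranded total RNA kit with removal of ribosomal RNA. The submitters' processing notes name STAR, SAMtools and RSEM, with no version, and the genome builds hg19 and mm10. Their settings, and how human and mouse reads were told apart, are not given in the sources used here.

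The authors deposited TPM, transcript abundances scaled to a fixed total, in 2 tables, 1 for human genes and 1 for mouse genes, and each library sums to about 1000000 in the mouse table and 999372 to 999553 in the human one. TPM keep no record of depth, so the depth of each library is unknown, and no counting interval or detection limit is given. The tables were scaled separately, so tests stayed within a table, and levels from both tables set side by side are on different scales. The share of mouse RNA in each tumour was therefore not computed. A value of 0 is called listed at 0, since it can also be a failed estimate. Among human genes, 28 had names turned into dates and were left out; they held at most 0.0628% of a library. Of the 26306 human names left, 23603 matched a current gene symbol of the GRCh38.p14 annotation, 1596 only an older symbol and 1107 neither; names are printed as deposited, and no coordinates are given. RSEM divides reads between near-identical copies, so values of single histone genes, small nucleolar RNAs, NCF1 and other genes with close copies are uncertain.

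Genes with a mean of at least 1 TPM were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1). The fit used a variance trend, an empirical Bayes spread, no covariates and the Benjamini-Hochberg adjustment, with a threshold of 0.05. The plan had foreseen a count test, with this test in its place should the tables hold TPM; the trend was not part of the plan. Folds and log2 changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. The human fit had 4.29 prior degrees of freedom. In the mouse table the estimate was infinite, so that genes of like level shared 1 spread, and a gene with a large value in a single library could pass. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so none was used. Tests were two-sided.

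Gene lists for pathways, complexes and cell types were tested against all other genes with limma's camera, with the correlation between genes preset at 0.01. The adjustment ran over the lists of a table with at least 3 measured members. Beside each call stands the camera p with a correlation estimated from the 4 libraries; fry, which asks whether genes of a list move on balance in a single direction, was the other alternative. The gene test was adjusted over all genes tested and again over each list alone. The human lists were p53 targets, interferon-stimulated genes, NF-kB targets, MLL fusion targets, MYC targets, S-phase genes, G2 and mitosis genes, FACT and histone chaperones, linker and core histones, heat shock genes, pro-apoptotic and anti-apoptotic BCL2 family genes, myeloid differentiation genes, primitive and granule myeloid genes, cholesterol biosynthesis genes, ATF4 and unfolded protein response genes, hypoxia genes, cytosolic ribosomal proteins, oxidative phosphorylation genes, and stromal and erythroid genes. The mouse lists held interferon-stimulated genes, p53 targets, NF-kB targets, S-phase genes, G2 and mitosis genes, MHC class I genes, hypoxia genes and cytosolic ribosomal proteins. They also held markers of macrophages, neutrophils, dendritic cells with MHC class II, natural killer cells, endothelium, pericytes and smooth muscle, fibroblasts, keratinocytes, adipocytes, skeletal muscle, erythroid cells and mast cells, and collagens and matrix genes.

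The groups, tests, lists, alternatives first listed and rule for named genes were fixed before the data were examined. The rule takes, per table, up to 8 genes with the largest rise and up to 8 with the largest fall past the threshold. Such genes need a mean log2 value of at least 3 and both treated values beyond both untreated values; small RNAs and unnamed loci are passed over. It adds the 2 members of each list past its test, and the 1 member of each other list, with the smallest p. In the human table it always takes SSRP1, SUPT16H, CDKN1A, MDM2, MYC, HOXA9, MEIS1, FLT3, KMT2A and AFF1, and in the mouse table Ssrp1, Supt16, Cdkn1a and Mdm2. A few genes that the rule takes are not reported here. The level of 3 was planned on log2 CPM and was applied to log2(TPM + 1).

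Alternatives were median-of-ratios scaling over genes with a mean of at least 10 TPM, no filter beyond TPM above 0, a mean of at least 10 TPM, a pseudocount of 0.1, the replicate number as a block, and each library left out in turn. Added after seeing the data were TPM rescaled without small structural RNAs, a fit with no variance trend, and a fit without genes whose same-named gene in the other table had a higher TPM in any library. Left out with the small structural RNAs were the humanin-like MTRNR2L genes of the human table and Rn45s and Lars2 of the mouse table. Counts over the list alone with a library left out were not part of the plan either. Both steps were tested on simulated data with known changes. Of 50 human genes changed by a log2 of 4, 36 were recovered, against 4 of 50 at a log2 of 2. There were 3 false calls among the unchanged of the 12510 genes. Single genes were changed only where their mean log2(TPM + 1) was at least 4, so recovery of lower genes is not covered. For mouse genes, 4 of 50 changed by a log2 of 4 were recovered, with 0 false calls among the unchanged of the 13101 genes. For human lists of 30 genes shifted by a log2 of 1, 20 of 20 were recovered and 0 of 400 unchanged lists were called. For the mouse table these were 18 of 20 and 1 of 400. The simulated genes were drawn independently, so these rates do not cover lists whose genes move together. In the real data, splits mixing treated and untreated tumours called 5 and 4 human lists and 7 and 6 mouse lists.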

Results

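RNA was sequenced from 4 tumours that MV4;11 cells had formed under the skin of NOD/SCID mice, a strain without functional T and B cells. MV4;11 is a human acute leukaemia line with a fusion of KMT2A (also called MLL) and AFF1 and an activating mutation of FLT3. From each of 2 groups, untreated mice and mice given CBL0137, 2 tumours were collected. CBL0137 is a curaxin, a small molecule that binds DNA and traps the histone chaperone FACT on chromatin. It was injected into a vein at 70 mg/kg on day 0 and day 8, from a tumour size of about 100 cubic millimetres. Treated tumours were collected 24 h after the last injection. For the untreated tumours the labels give no injections, starting size or collection time, so a match in these cannot be checked. The comparison asks how the drug alters gene expression in the leukaemia cells and in the mouse cells of the same tumours. Values for 26306 human and 24411 mouse genes were given as TPM, transcript abundances scaled to a fixed total within each table, with unknown sequencing depth. Per tumour, 11517 to 13501 human and 11964 to 13242 mouse genes reached 1 TPM.

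CBL0137 replicate 1 stood apart from the other tumours. Across human genes, which are not independent replicates, its Pearson correlation with the others was 0.795 to 0.842, against 0.910 to 0.971 among the others. Its humanin-like MTRNR2L genes, near copies of mitochondrial ribosomal RNA, summed to 76147 TPM, against 5102 to 6996 TPM elsewhere. Small structural RNAs, counted with the MTRNR2L genes, took 51.3%, 57.9%, 58.4% and 56.1% of human TPM in untreated 1, untreated 2, CBL0137 1 and CBL0137 2. In the mouse table these shares were 31.5%, 61.7%, 80.0% and 36.2%, counted with the ribosomal precursor Rn45s and the gene Lars2. Rn45s was at 49150, 367123, 585605 and 164311 TPM in that order, and alone took 58.6% in CBL0137 replicate 1. Lars2 was at 2286, 85582, 132974 and 14896 TPM. The mouse shares are therefore not those of small RNAs alone. The median-of-ratios scaling factors of the mouse libraries were 1.56, 0.84, 0.49 and 1.54 in the same order. Mouse TPM of single genes are printed without this scaling, so those of CBL0137 replicate 1 stand low beside the others. The labels do not say whether each tumour came from its own mouse, so the limma p-values measure only the spread between these 4 samples. Camera with the preset correlation compares genes with genes, so its p-values do not measure the spread between tumours.

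Genes of DNA replication and cell division fell in the human cells of the treated tumours. All 42 measured S-phase genes, which serve DNA synthesis, were lower in both treated than in both untreated tumours. So were 48 of 53 genes of G2 and mitosis. Chance gives 16.7% for a single gene, and 12.2% of all human genes tested lay lower in this way. Genes of a list can move together, so its members are not independent results. RRM2, a subunit of the enzyme that makes deoxyribonucleotides, was at 118 ± 16.2 TPM (SD, n = 2) in untreated and 8.61 ± 1.22 TPM in treated tumours. That is a log2 change of -3.63 (SE 0.37), or 12.3-fold lower, with a limma adjusted p of 0.00196 over the list alone and 0.0884 over all genes. Over all genes RRM2 passed without untreated replicate 1 (limma adjusted p = 0.0197), untreated replicate 2 (0.00582), CBL0137 replicate 1 (0.04998) or CBL0137 replicate 2 (0.0323), and with a mean of at least 10 TPM (0.0482). TYMS, thymidylate synthase, went from 92.8 ± 18.6 to 10.9 ± 2.75 TPM. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, went from 63.9 ± 15.4 to 5.67 ± 3.02 TPM, and KIF2C, a mitotic kinesin, from 35.4 ± 7.35 to 4.93 ± 0.417 TPM. The median log2 change was -2.13 for the S-phase list and -2.22 for the mitosis list, against 0.26 for all genes tested. Adjusted over the list alone, 38 of 42 S-phase and 41 of 53 mitosis genes fell, and none rose, against 0 over all genes tested.

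Histones fell with them. Of 37 linker and core histone genes, 31 were lower in both treated tumours, 29 fell and 1 rose when adjusted over the list alone, 0 did so over all genes tested, and the median log2 change was -2.41. The core histone gene HIST1H3B was at 753 ± 229 TPM in untreated and 42.4 ± 15.3 TPM in treated tumours, and HIST1H2BO at 228 ± 36.8 and 21.5 ± 0.156 TPM; single values of such near-identical copies are uncertain. Over all genes HIST1H2BO passed without any 1 of the 4 tumours (limma adjusted p of 0.0130 to 0.04998), HIST1H3B without any of them but CBL0137 replicate 1, and both with a mean of at least 10 TPM (0.0482). The gene that rose, H1F0, chosen after its values were seen, encodes a linker histone made outside S phase, and went from 2.72 ± 1.44 to 8.05 ± 0.191 TPM. Its call ended without untreated replicate 1, without untreated replicate 2 and without genes higher in the mouse table. Camera with the preset correlation gave adjusted p = 2.06e-53 for the S-phase list, 2.06e-53 for the mitosis list and 3.84e-40 for histones, and for each of the 3 lists adjusted p = 0.242 with an estimated correlation. Relative to all genes, their medians were -2.45, -2.72 and -2.90 in CBL0137 replicate 1 and -2.25, -1.96 and -2.38 in replicate 2. Without untreated replicate 1, 22 S-phase and 21 mitosis genes fell over the list alone. Without genes that were higher in the mouse table in any library, 20 of 21 S-phase and 24 of 32 mitosis genes did.

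Interferon-stimulated genes rose in the human cells. All 39 measured members, which act largely in antiviral defence, were higher in both treated tumours, with a median log2 change of 1.96. Of all human genes tested, 30.9% were higher in both. Adjusted over the list alone 36 of 39 rose, against 0 over all genes tested. MX2, an antiviral GTPase, was at 2.04 ± 0.679 TPM in untreated and 31.8 ± 2.97 TPM in treated tumours, a log2 change of 3.45 (SE 0.39; limma adjusted p = 0.00163 over the list alone, 0.0884 over all genes). IFI27 went from 0.455 ± 0.205 to 17.8 ± 4.66 TPM. This list had a camera adjusted p of 2.66e-30, and adjusted p = 0.242 with an estimated correlation. The list's median relative to all genes was 1.70 in CBL0137 replicate 1 and 1.85 in replicate 2. Over all genes the 0 members called became 5 without untreated replicate 1, 3 without untreated replicate 2, 28 without CBL0137 replicate 2 and 2 with a mean of at least 10 TPM. The 36 members over the list alone became 17 without untreated replicate 2, and 7 of the 8 members left when genes higher in the mouse table in any library were taken out.

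Targets of p53, the tumour suppressor that answers DNA damage, also rose as a list. Of 28 measured members 21 were higher in both treated tumours and the median log2 change was 1.22. Adjusted over the list alone 10 rose, against 0 over all genes tested. CDKN1A, an inhibitor of cell cycle kinases, was at 31.7 ± 1.73 TPM in untreated and 163 ± 23.2 TPM in treated tumours (log2 change 2.32, SE 0.36; limma adjusted p = 0.0162 over the list alone, 0.110 over all genes). MDM2, the ligase that degrades p53, went from 66.0 ± 6.89 to 261 ± 97.9 TPM, and BTG2, an antiproliferative gene, from 4.10 ± 0.0636 to 17.7 ± 0.983 TPM. For this list the camera adjusted p was 5.60e-09, and adjusted p = 0.242 with an estimated correlation. The 10 members became 0 without untreated replicate 1, 0 without untreated replicate 2, 17 without CBL0137 replicate 1, and 0 of 15 without genes higher in the mouse table, while the list kept its camera call in each case. Without CBL0137 replicate 2, 1 target was called lower over the list alone.

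**Figure D1:**
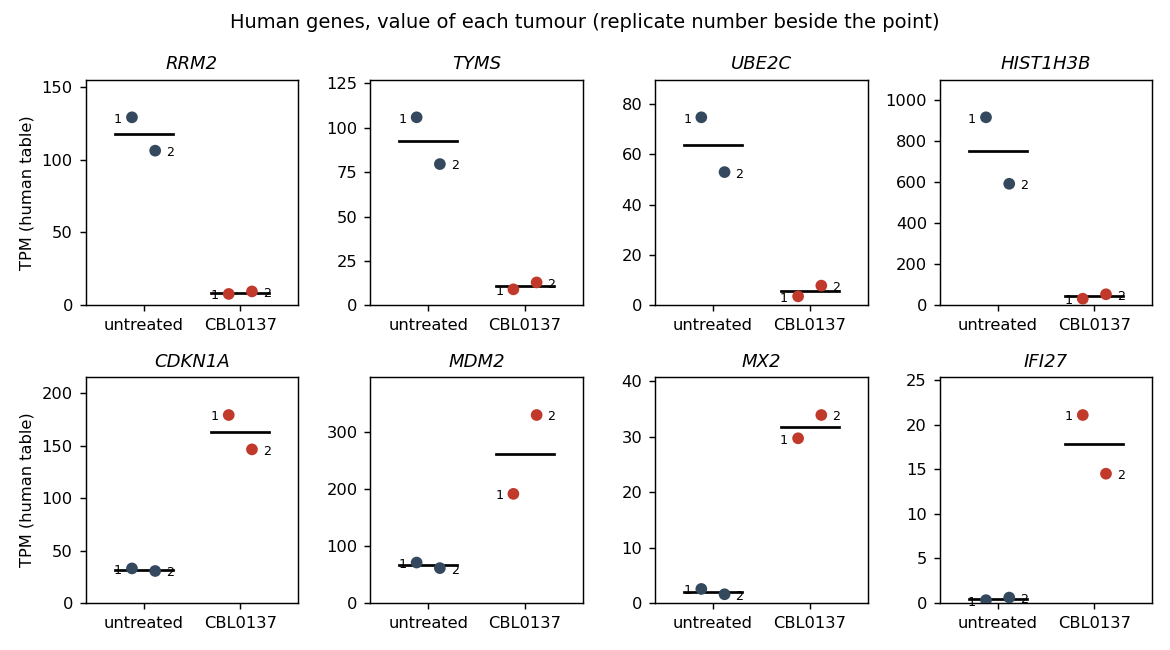
TPM of 8 human genes, each on its own linear axis from 0, with 1 point per tumour and bars at the group mean. RRM2, TYMS, UBE2C and HIST1H3B lie lower and CDKN1A, MDM2, MX2 and IFI27 higher in both CBL0137 tumours, for example 179 and 147 against 32.9 and 30.5 TPM for CDKN1A.

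The NF-kB and myeloid differentiation lists rose with less support. Among 19 NF-kB targets, genes of inflammation and survival, 1 rose over the list alone and 0 over all genes: CXCL10, a chemokine also induced by interferon, from 1.10 ± 0.368 to 9.20 ± 2.96 TPM. TNFAIP2 was at 11.7 ± 2.16 and 46.5 ± 27.5 TPM. The NF-kB median was 0.89 (camera adjusted p = 0.00491; adjusted p = 0.537 with an estimated correlation), and relative to all genes 0.81 in CBL0137 replicate 1 but 0.22 in replicate 2. Without untreated replicate 1 or 2 the count over the list alone was 0, and it was 8 without CBL0137 replicate 2. The NF-kB call ended without CBL0137 replicate 1 (camera adjusted p = 0.129) and with no filter on low values (0.0793), and the list could not be tested without genes higher in the mouse table, where 1 target was left. Among 21 myeloid differentiation genes 1 rose over the list alone and 0 over all genes: NCF1, a subunit of the phagocyte oxidase with near-identical pseudogenes, from 9.51 ± 0.0212 to 43.1 ± 4.43 TPM. The list's median was 0.76 (camera adjusted p = 0.00582; adjusted p = 0.269 with an estimated correlation), and relative to all genes 0.27 in CBL0137 replicate 1 and 0.97 in replicate 2. Its count over the list alone was 0 without untreated replicate 1 or 2, 9 without CBL0137 replicate 1, 5 without CBL0137 replicate 2 and 4 without small structural RNAs. The myeloid call ended without untreated replicate 1 (camera adjusted p = 0.230), without CBL0137 replicate 2 (0.475) and without genes higher in the mouse table (0.989).

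Genes of chromatin assembly fell as a list. Of 15 FACT and histone chaperone genes 3 fell over the list alone, against 0 over all genes: ASF1B, MCM2 and CHAF1B, all of which act at replicating chromatin, the last 2 also being in the S-phase list. ASF1B, a chaperone for histones H3 and H4, went from 29.7 ± 5.59 to 3.98 ± 0.686 TPM, MCM2, part of the replicative helicase, from 64.1 ± 18.5 to 10.7 ± 4.74 TPM, and CHAF1B from 11.9 ± 3.73 to 1.87 ± 1.02 TPM. The FACT subunits themselves did not pass (limma adjusted p = 0.568 and 0.599): SSRP1 was at 81.5 ± 24.1 and 44.3 ± 8.27 TPM and SUPT16H at 81.2 ± 5.74 and 53.2 ± 10.3 TPM. The list's median was -0.61 (camera adjusted p = 3.88e-06; adjusted p = 0.269 with an estimated correlation). Relative to all genes the median was -1.02 in CBL0137 replicate 1 and -0.57 in replicate 2. The 3 members became 0 without untreated replicate 1, 6 without CBL0137 replicate 1 and 0 of 5 without genes higher in the mouse table.

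Lists of synthesis and metabolism fell by smaller amounts than the S-phase, mitosis and histone lists. The median log2 change relative to all genes was -0.96 for 23 cholesterol biosynthesis genes, -0.76 for 41 oxidative phosphorylation genes, -0.69 for 42 cytosolic ribosomal proteins, -0.69 for 22 heat shock genes and -0.65 for 30 MYC targets. In that order the camera adjusted p was 4.47e-08, 8.89e-10, 1.21e-09, 5.09e-05 and 2.74e-06, and adjusted p = 0.242, 0.358, 0.380, 0.269 and 0.348 with an estimated correlation. No member of these 5 lists passed over the list alone or over all genes with limma; at an unadjusted p under 0.05, 8 cholesterol genes were lower and 1 higher, and 1 MYC target was lower. SQLE, squalene epoxidase, was at 13.4 ± 0.332 and 3.73 ± 1.1 TPM. HSPD1, a mitochondrial chaperone in both the MYC and heat shock lists, was at 407 ± 31.9 and 234 ± 38.1 TPM, CDK4 at 64.0 ± 14.8 and 27.1 ± 1.73 TPM, and AHSA1, an HSP90 activator, at 106 ± 14.4 and 56.0 ± 13.0 TPM. Relative to all genes the ribosomal, oxidative phosphorylation and heat shock medians, -1.06, -1.06 and -1.05 in CBL0137 replicate 1, were -0.33, -0.37 and -0.45 in replicate 2. RPL14 was at 599 ± 29.4 and 341 ± 101 TPM, RPSA at 989 ± 160 and 565 ± 195 TPM, UQCRH at 345 ± 37.2 and 201 ± 47.7 TPM and ATP5B at 396 ± 38.8 and 240 ± 43.5 TPM. The heat shock call ended without untreated replicate 2 (camera adjusted p = 0.0885), and without CBL0137 replicate 2, 10 cholesterol and 13 oxidative phosphorylation genes fell over the list alone while 1 cholesterol and 1 heat shock gene rose. Cholesterol genes called lower over the list alone were 1 without CBL0137 replicate 1 and 3 without genes higher in the mouse table.

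The leukaemia's own programme did not pass its test. For 19 targets of MLL fusions the median log2 change was 0.19, while the test pointed down (camera adjusted p = 0.939), and 0 passed with limma, 0 also at an unadjusted p under 0.05. HOXA9 and MEIS1, transcription factors that sustain such leukaemias, were at 14.5 ± 3.27 and 23.1 ± 1.52 TPM and at 35.9 ± 0.863 and 42.6 ± 0.247 TPM in untreated and treated tumours. RUNX1 was at 50.4 ± 11.0 and 109 ± 45.6 TPM, KMT2A at 16.2 ± 2.69 and 21.6 ± 4.2, AFF1 at 27.1 ± 3.86 and 32.3 ± 0.170, the receptor kinase FLT3 at 177 ± 31.4 and 111 ± 23, and MYC at 116 ± 35.1 and 83.2 ± 37.3 TPM. None of these 7 passed over all genes (limma adjusted p of 0.537 to 0.805).

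Other human lists did not pass either. The camera adjusted p was 0.199 for 9 pro-apoptotic and 0.286 for 5 anti-apoptotic BCL2 family genes, 0.727 for 17 hypoxia genes and 0.765 for 13 primitive and granule myeloid genes. It was 0.595 for 23 ATF4 and unfolded protein response genes, whose test pointed down with a median of 0.086, or -0.024 after median-of-ratios scaling. There PHGDH, which opens serine synthesis, fell over the list alone, at 6.77 and 4.03 TPM in untreated and 0 and 0.090 TPM in treated tumours; this count was 0 without untreated replicate 1. Without CBL0137 replicate 2, 4 pro-apoptotic and 3 hypoxia genes rose over the list alone, 2 primitive and granule myeloid genes fell, and of the ATF4 list 2 rose and 2 fell. Without CBL0137 replicate 1, 2 primitive and granule myeloid genes rose. BCL2L11, which encodes the death promoter BIM, was at 5.44 ± 0.0212 and 17.3 ± 4.96 TPM, the survival gene MCL1 at 64.4 ± 5.01 and 99.7 ± 22.8, the stem cell factor receptor KIT at 6.59 ± 0.0212 and 3.20 ± 2.37, and NDRG1 at 25.2 ± 1.05 and 59.9 ± 6.47 TPM. As a check on mouse RNA in the human table, 5 of 24 stromal genes were measured (camera adjusted p = 0.339, SPARC 1.16 ± 0.523 and 4.91 ± 2.44 TPM) and 0 of 11 erythroid genes. With low values kept, the erythroid mean log2(TPM + 1) was 0.0101 and 0.0154 in untreated 1 and 2. It was 0.393 and 0.0997 in CBL0137 1 and 2. The stromal mean was 0.630 and 0.534 in the untreated and 0.903 and 0.692 in the CBL0137 tumours. Without CBL0137 replicate 2, 2 of the 5 stromal genes rose and 1 fell over the list alone, and SPARC passed over all genes (limma adjusted p = 0.0415).

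**Figure D2:**
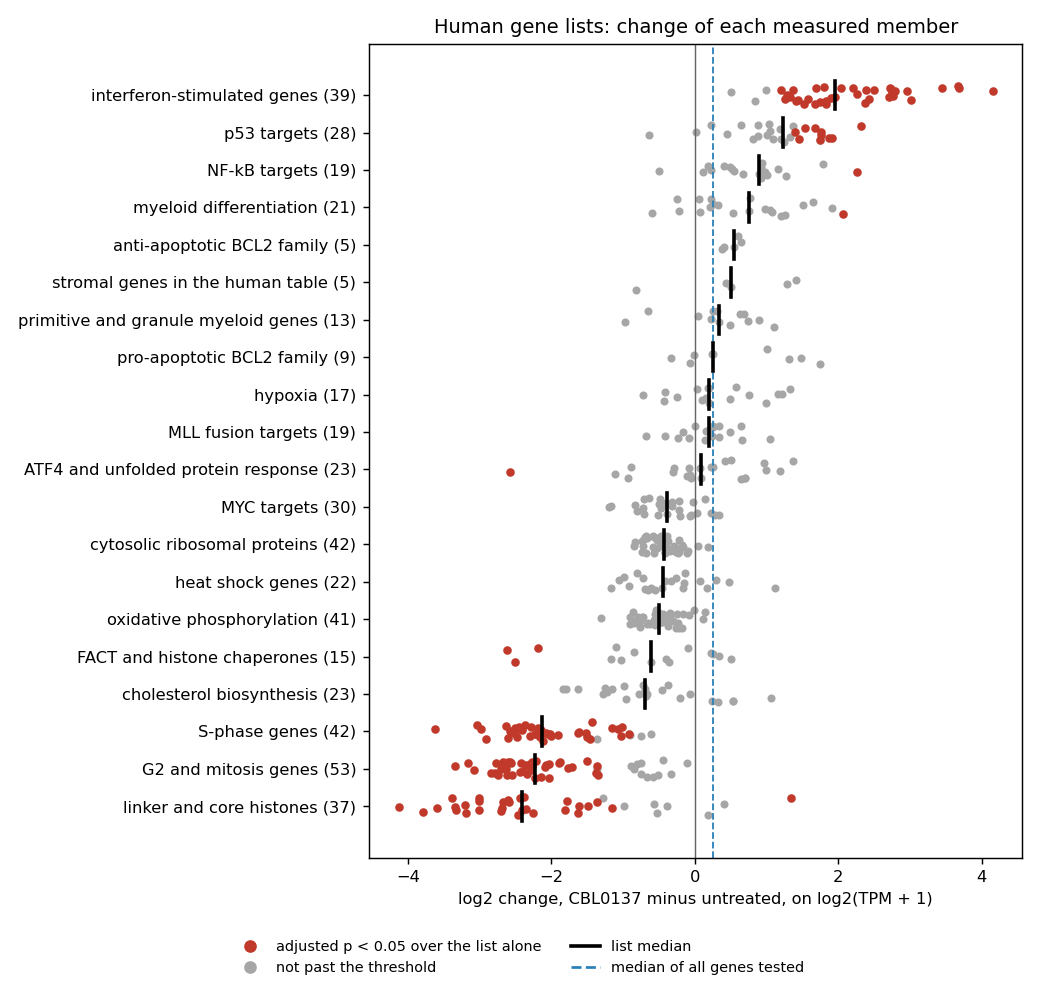
Log2 change (CBL0137 minus untreated, on log2(TPM + 1)) of each measured member of the 20 human lists, with red points for members past the threshold over the list alone, black bars at list medians and a dashed line at the median of all genes. Medians run from -2.41 for histones to 1.96 for interferon-stimulated genes, around 0.26 for all genes.

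Over all human genes, limma called 4 of 12510 at an adjusted p under 0.05, all lower and all small RNAs that guide RNA modification, named here after their values were seen. SNORA11B was at 40.3 and 51.7 TPM in the untreated tumours. SCARNA14 was at 39.9 and 24.5 TPM there, and SNORA55 and SNORA75 had identical values of 19.9 and 24.5 TPM. All 4 were listed at 0 in both treated tumours (limma adjusted p = 0.0481). SCARNA14, SNORA55 and SNORA75 shared a value in untreated replicate 2. With depth unknown, these calls may rest on few reads. At an unadjusted p under 0.05, 755 genes were higher and 426 lower. Both treated tumours lay above both untreated ones for 30.9% of genes and below for 12.2%, where chance gives 16.7% each. The median log2 change of all genes was 0.26, and 0.15 after median-of-ratios scaling, which left 0 calls (1214 at an unadjusted p under 0.05). The count was 44 without untreated replicate 1, 60 without untreated replicate 2, 14 without CBL0137 replicate 1 and 1638 without CBL0137 replicate 2. In all, 13 of 20 lists passed with the preset correlation, 4 up and 9 down, and 0 with an estimated correlation or with fry.

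In the mouse cells of the same tumours interferon-stimulated genes rose. Of 40 measured members 38 were higher in both treated tumours, against 7.27% of all mouse genes tested. The median log2 change was 3.21, against -0.29 for all mouse genes. Adjusted over the list alone 26 of 40 rose, against 2 over all genes tested. These were Mx2, an antiviral GTPase, at 1.83 ± 0.933 TPM in untreated and 126 ± 37.0 TPM in treated tumours (log2 change 5.50, SE 1.18; limma adjusted p = 0.00566), and Ifit3b, of a family that binds viral RNA, at 7.82 ± 5.98 and 380 ± 205 TPM (5.51, SE 1.35; 0.0400). Camera gave an adjusted p of 1.05e-95, and adjusted p = 0.482 with an estimated correlation. After median-of-ratios scaling, which moved the median of all mouse genes from -0.29 to 0.045, 39 members rose over the list alone. Relative to all genes the list's median was then 3.56 in CBL0137 replicate 1 and 3.39 in replicate 2. Over the list alone 0 rose without untreated replicate 1 and 0 without untreated replicate 2, while the list kept its camera call in both cases, and 38 rose without CBL0137 replicate 1.

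MHC class I genes, which present peptides on the cell surface, rose as well. Of 15 members 14 were higher in both treated tumours, with a median log2 change of 1.73. Over the list alone 1 rose, H2-T22, a class I molecule listed at 0 and 11.7 TPM in untreated and at 69.1 and 111 TPM in treated tumours; 0 rose over all genes, and 14 over the list alone after median-of-ratios scaling. Nlrc5, the activator of class I transcription, was at 6.33 ± 4.87 and 34.8 ± 3.62 TPM. The camera adjusted p was 7.47e-20, and adjusted p = 0.482 with an estimated correlation. The 1 member became 0 without untreated replicate 1, 3 without CBL0137 replicate 1 and 2 without CBL0137 replicate 2.

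Markers of fat rose and those of skeletal muscle fell, unevenly between tumours. All 13 measured adipocyte markers were higher in both treated tumours, with a median of 2.21 (camera adjusted p = 5.73e-24; adjusted p = 0.482 with an estimated correlation). Over the list alone 3 rose, Plin1, Cidec and Retn, against 1 over all genes and 12 over the list alone after median-of-ratios scaling. The lipid droplet gene Cidec was at 17.1 ± 19.0 and 144 ± 11.4 TPM, and Plin1, which coats lipid droplets, at 7.83 ± 8.72 and 64.4 ± 40.0 TPM. The hormone gene Retn was listed at 0 in both untreated tumours and at 83.0 and 17.1 TPM in the treated ones (limma adjusted p = 0.000291 over all genes, but 0.217 after median-of-ratios scaling, 0.126 without small structural RNAs and 0.555 with a mean of at least 10 TPM). The 3 members became 0 without untreated replicate 1 and 0 without untreated replicate 2. The 16 muscle markers had a median of -2.36 (camera adjusted p = 2.35e-21; adjusted p = 0.631 with an estimated correlation). After scaling, their median relative to all genes was 0.19 in CBL0137 replicate 1 and -4.45 in replicate 2. Pvalb, a calcium buffer of fast fibres, fell over the list alone, at 106 and 42.2 TPM in untreated and 31.9 and 0 TPM in treated tumours, and Mylpf, a myosin light chain, was at 427, 327, 121 and 8.47 TPM. The Pvalb call ended without untreated replicate 1, untreated replicate 2 or CBL0137 replicate 2, and also after median-of-ratios scaling or without small structural RNAs. Without CBL0137 replicate 2 the muscle list turned to a mean of 0.019 above all genes (camera adjusted p = 0.949), and without CBL0137 replicate 1 all 16 members fell over the list alone. Keratinocyte markers did not pass (15 measured; camera adjusted p = 0.187), and their median, -0.51, was 0.21 after scaling. Without CBL0137 replicate 1 or untreated replicate 2 they passed as lower (camera adjusted p = 1.03e-19 and 5.69e-12), and without CBL0137 replicate 2 as higher (1.45e-08), as also without untreated replicate 1 (1.52e-06). Their median relative to all genes after scaling was 1.94 in CBL0137 replicate 1 and -1.87 in replicate 2, and Dmkn was at 25, 2.87, 9.51 and 0 TPM in untreated 1, untreated 2, CBL0137 1 and CBL0137 2.

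**Figure D3:**
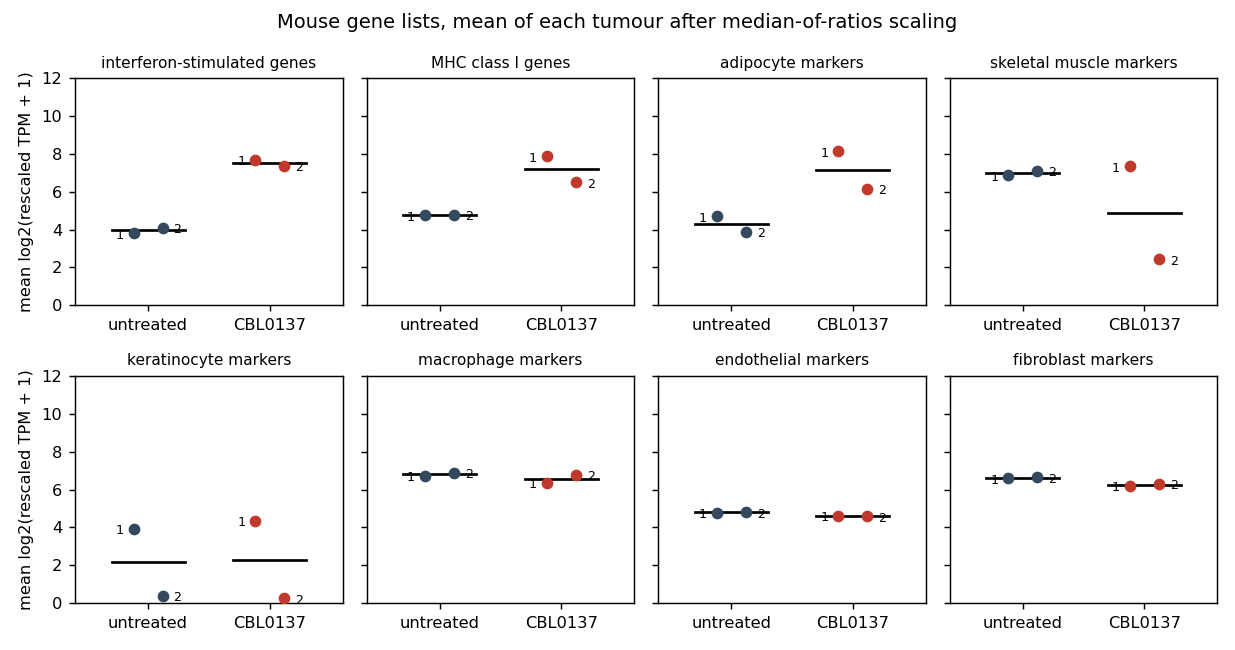
Mean log2(TPM + 1) after median-of-ratios scaling of 8 mouse gene lists, with 1 point per tumour, numbered by replicate, and bars at group means. Interferon-stimulated genes sit at 3.81 and 4.11 in untreated and 7.68 and 7.37 in CBL0137 tumours, while muscle markers sit at 7.35 and 2.44 in the CBL0137 tumours.

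Stromal, growth and other lists moved by smaller amounts, and all calls in this paragraph had adjusted p = 0.831 with an estimated correlation. Relative to all mouse genes, median log2 changes were -0.65 for 41 G2 and mitosis genes (camera adjusted p = 2.08e-04), -0.50 for 32 S-phase genes (0.00283), -0.54 for 42 ribosomal proteins (3.95e-04), -0.53 for 25 collagen and matrix genes (0.00684), -0.65 for 17 fibroblast markers (0.0455), -0.40 for 13 pericyte and smooth muscle markers (0.0263) and -1.05 for 11 genes of dendritic cells and MHC class II (0.0455). The medians were 0.49 for 28 p53 targets (0.00345) and 1.49 for 4 mast cell markers (0.0107). With limma 0 members of these 9 lists passed over the list alone; at an unadjusted p under 0.05, 3 mitosis genes, 3 S-phase genes and 1 pericyte gene were lower and 1 p53 target higher. These counts over the list alone moved with the setting. Without CBL0137 replicate 2, 3 S-phase, 1 mitosis, 1 pericyte, 3 fibroblast and 1 collagen list gene were called lower, and without untreated replicate 2, 1 mitosis and 1 pericyte gene. After median-of-ratios scaling 2 S-phase genes were called lower and 1 p53 target higher, and without small structural RNAs 2 S-phase genes lower and 2 p53 targets and 2 mast cell genes higher. Of the S-phase and mitosis lists 0 members were left without genes higher in the human table. Both lists also fell in the human table, so human reads counted as mouse may contribute to their fall here. This was not tested. Mcm4, part of the replicative helicase, was at 146 ± 54.1 and 14 ± 15.4 TPM, Hells at 43.2 ± 17.5 and 9.33 ± 10.8 TPM, the mitotic kinase gene Plk1 at 11.1 ± 9.89 and 0.610 ± 0.297 TPM and Cdca8 at 8.35 ± 0.933 and 1.42 ± 1.22 TPM. Cdkn1a was at 24.6 ± 14.3 and 134 ± 89.7 TPM (limma adjusted p = 1.00; 0.0441 after scaling), Mdm2 at 19.5 ± 8.06 and 47.4 ± 32.4, and Gdf15 at 2.85 and 0 in untreated and 4.42 and 16.3 TPM in treated tumours. The FACT genes Ssrp1 and Supt16 were at 49.3 ± 26.4 and 33.8 ± 20.3 TPM and at 42.2 ± 18.2 and 32.7 ± 26.3 TPM. Their log2 changes, -0.56 and -0.55, were both -0.18 after median-of-ratios scaling.

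Several of those calls rested on single tumours. Without CBL0137 replicate 1, in which Col12a1 was at 26.3 TPM against 563 to 661 elsewhere, the camera adjusted p was 0.617 for fibroblasts, 0.354 for collagens, 0.116 for ribosomal proteins, 0.116 for pericytes and 0.150 for mast cells. Without CBL0137 replicate 2 it was 0.108 for p53 targets and 0.817 for the dendritic cell list. Without untreated replicate 1 it was 0.114 for fibroblasts and 0.0984 for pericytes, and the dendritic cell list turned to a mean of 0.038 above all genes; H2-Eb1, an MHC class II chain, was at 180 TPM in that tumour and at 20.5, 21.1 and 11.1 TPM in the others. Without untreated replicate 2 it was 0.195 for fibroblasts and 0.239 for mast cells. Median-of-ratios scaling ended the pericyte (0.0875) and dendritic cell (0.0931) calls, as did leaving out small structural RNAs (0.0736 for both). The call also ended with no filter for mast cells (0.0897) and fibroblasts (0.0503), and without genes higher in the human table for pericytes (0.105). Lum, a matrix proteoglycan of fibroblasts, was at 237, 179, 16.2 and 175 TPM in untreated 1, untreated 2, CBL0137 1 and CBL0137 2, and Fap at 68.7, 40.8, 5.14 and 59.8. The elastin gene Eln was at 298, 119, 41.8 and 81.7 TPM, the ribosomal genes Rps25 at 484, 431, 40.5 and 491 and Rpl30 at 120, 63.4, 7.20 and 46.0, and the smooth muscle genes Tagln at 226, 112, 9.16 and 151 and Cnn1 at 5.79, 1.54, 0 and 0 TPM. Ciita, the activator of MHC class II, was at 11.7, 2.12, 1.86 and 0.320 TPM, and the mast cell genes Tpsb2 at 0, 0, 1.76 and 3.61 and Hdc at 4.73, 0.630, 8.76 and 8.96 TPM.

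The remaining mouse lists did not pass with all 4 tumours, though some did with 1 left out: macrophage markers lower without CBL0137 replicate 2 (camera adjusted p = 0.0127), natural killer markers higher without untreated replicate 1 (0.00382) or CBL0137 replicate 2 (0.00518), and erythroid genes higher without CBL0137 replicate 1 (0.000599) but lower without replicate 2 (0.00518). The camera adjusted p was 0.141 for 21 macrophage markers (Cd14 at 26.2 ± 5.23 and 6.09 ± 4.0 TPM), 0.165 for 22 endothelial markers (Aplnr at 74.2 ± 31.6 and 22.9 ± 23.2 TPM) and 0.644 for 21 hypoxia genes (Car9 at 4.41 and 3.13 in untreated and 0.450 and 0 TPM in treated tumours). The hypoxia median, -0.41, was 0.058 once small structural RNAs were left out. For 8 natural killer cell markers it was 0.165, with a median of -0.18 but a mean of 0.26 and a test pointing up, and Gzmb, a killing protease, rose over the list alone (2.10 and 0 TPM untreated, 11.7 and 9.33 treated). Only 4 of these 8 markers were left to test without untreated replicate 1. For 27 NF-kB targets the camera adjusted p was 0.172, with a median of -0.078, a mean of 0.045 and a test pointing up, and 1 member, Cxcl10, rose. Both medians turned positive after median-of-ratios scaling, 0.21 and 0.22. For 6 neutrophil markers it was 0.754, with a median of 0.23, a mean of -0.12 and a test pointing up. Over the list alone S100a9 fell (21.4 and 16 TPM untreated, 0 and 4.63 treated) and Lcn2, chosen after its values were seen, rose, from 2.93 ± 1.22 to 68.9 ± 87.5 TPM. For 9 erythroid genes it was 0.458, and Hba-a2, an alpha globin, fell over the list alone, at 662, 302, 0 and 411 TPM in untreated 1, untreated 2, CBL0137 1 and CBL0137 2. The Gzmb call ended without any 1 of the 4 tumours, the Cxcl10 call over the list alone without untreated replicate 1 or 2, and the Lcn2 call without untreated replicate 1, untreated replicate 2 or CBL0137 replicate 2. The S100a9 call ended without untreated replicate 1 or CBL0137 replicate 1, and the Hba-a2 call without untreated replicate 1, untreated replicate 2 or CBL0137 replicate 1. The Gzmb and Hba-a2 calls also ended after median-of-ratios scaling and without small structural RNAs, the Gzmb call with no filter, and the S100a9 call without genes higher in the human table.

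Over all mouse genes limma called 14 of 13101, 11 higher and 3 lower (429 at an unadjusted p under 0.05). Beside Mx2 and Ifit3b, the higher genes included Ifit1bl1, listed at 0 and 1.37 TPM in untreated and at 102 and 408 TPM in treated tumours (adjusted p = 1.08e-05). The chemokine genes Cxcl10 and Cxcl11, which attract T cells, rose too. Cxcl10 went from 3.56 ± 2.89 to 209 ± 183 TPM (log2 change 5.35, SE 1.24; limma adjusted p = 0.0184), and Cxcl11 was at 0 and 1.98 in untreated and 23.5 and 64.6 TPM in treated tumours (0.0165). Gbp11, an interferon-induced GTPase, went from 1.07 ± 0.0424 to 72.5 ± 24.0 TPM (5.11, SE 1.10; 0.00570). Of genes named after their values were seen, Ubd, a ubiquitin-like modifier, was at 0 in both untreated tumours and at 35.7 and 43.2 TPM in the treated ones, and BC094916 was at 0, 1.25, 17.2 and 40.6 TPM. The lower Gm14288 was at 21.8, 16.9, 0.300 and 0 TPM. Of 4 small RNAs called, Snora43 was at 0 in both untreated tumours and at 113 and 262 TPM in the treated ones, while Snora34, Snora64 and Snora7a were above 0 in a single tumour each. After median-of-ratios scaling 68 genes passed, 67 higher and 1 lower, 6 of them among the 14, including Ifit1bl1, Mx2, Cxcl10, Gbp11 and Ubd. Ifit3b and Cxcl11 did not pass there (limma adjusted p = 0.0572 and 0.0674), and Cxcl11 did not pass with no filter (0.0714), a mean of at least 10 TPM (0.477) or small structural RNAs left out (0.0830) either. Leaving out small structural RNAs gave 90, 89 of them higher. The count was 0 without untreated replicate 1 (limma; 181 at an unadjusted p under 0.05), 115 without CBL0137 replicate 1 (86 higher) and 48 without CBL0137 replicate 2 (16 higher). It was 104 without untreated replicate 2, all of them lower, so 0 of the 11 higher genes kept their call there (Ifit1bl1, limma adjusted p = 0.0615; Mx2, 0.451; Cxcl10, 0.776; Gbp11, 0.489). Of 21 lists 13 passed with the preset correlation, 5 up and 8 down, and 0 with an estimated correlation or with fry.

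**Figure D4:**
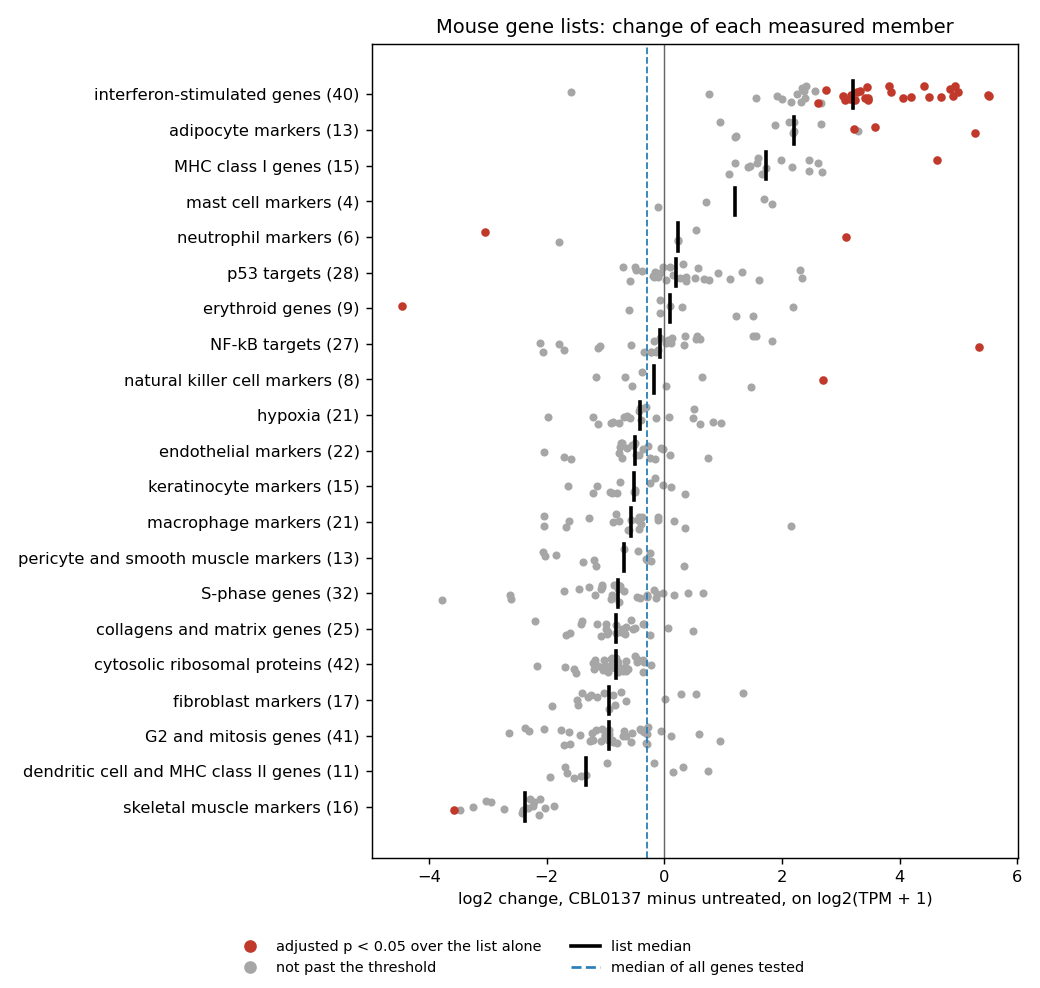
Log2 change (CBL0137 minus untreated, on log2(TPM + 1)) of each measured member of the 21 mouse lists, with red points for members past the threshold over the list alone, black bars at list medians and a dashed line at the median of all genes. Medians run from -2.36 for muscle to 3.21 for interferon-stimulated genes; that of keratinocyte markers (-0.51), like those of NF-kB targets and natural killer cells, turns positive after median-of-ratios scaling.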

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

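Counts of single genes moved under most alternatives, and the 13 human and 13 mouse lists past camera's test became 0 with an estimated correlation and 0 with fry. The rescaling without small structural RNAs, the fit with no variance trend and the fit without genes higher in the other table were chosen after seeing the data. Counts over the list alone with a tumour left out were not planned either. Outside the estimated correlation and fry, 169 of 177 human list comparisons kept direction and side of the threshold, 6 lost the call and 2 changed direction, and for human named genes 406 of 469 did so and 63 gained a call. For mouse genes, 148 of 185 list comparisons held, 18 lost and 6 gained a call and 13 changed direction; of 452 for named genes 397 held, 30 lost, 19 gained and 6 changed direction. No human named gene passed over all genes in the fit reported (lowest limma adjusted p = 0.0884), so none could lose a call. Most mouse named genes did not pass there either. For named genes, holding therefore mostly means staying uncalled. The cause of the changes between settings was not tested. Where a tumour is left out, the lone one of its group is assumed to vary like the other group. Tests planned on counts, and the mouse share of reads with its alternatives, were not run, since the tables hold TPM; library totals alone and the log2(TPM + 1) tests coincide with the fit reported, and a planned mean of 10 CPM was run as 10 TPM. With no depth known, low values have no stated precision.

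Against 4 human genes, limma called 0 with median-of-ratios scaling (1214 at an unadjusted p under 0.05), 0 with no filter beyond TPM above 0 (1372), 0 without small structural RNAs (1476) and 35 with a mean of at least 10 TPM, 31 of them lower. Leaving out each tumour gave 14 to 1638 human genes and 0 to 115 mouse genes, all 104 of those without untreated replicate 2 being lower. Against 14 mouse genes there were 68 with median-of-ratios scaling, 7 with a mean of at least 10 TPM, 46 with a pseudocount of 0.1 (22 higher, 24 lower), 90 without small structural RNAs and 53 with no variance trend. Without genes higher in the other table, only 8 of 17 mouse lists passed, fewer lists being testable.

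With the replicate number as a block, 1430 human genes (938 higher) and 0 mouse genes (159 at an unadjusted p under 0.05) passed, and 13 lists in each table. The labels do not say that the numbers mark a shared mouse or day; the deviations of same-numbered tumours correlated at 0.55 in the human and 0.20 in the mouse table over only 2 pairs, too few to tell whether the numbers pair the tumours. Over all human genes 36 interferon-stimulated genes were called with the block. Over the list alone, the block took interferon-stimulated mouse genes from 26 to 0, adipocyte markers from 3 to 1, and the single calls among MHC class I, muscle, erythroid, natural killer and NF-kB genes and both neutrophil calls to 0. In the human table it took p53 targets from 10 to 23, NF-kB targets from 1 to 8, myeloid differentiation from 1 to 8, FACT and histone chaperones from 3 to 6, cholesterol genes from 0 to 9 lower and 1 higher, and ATF4 genes from 1 lower to 3 lower and 2 higher. From 0 it called 2 MYC targets lower, and 4 pro-apoptotic, 3 hypoxia and 2 stromal genes higher.

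Directions changed as follows, given for lists as the mean less that of all genes and for genes as the log2 change. Keratinocyte markers were at 0.052 with median-of-ratios scaling. Neutrophil markers were at -0.11 with no filter and -0.16 without small structural RNAs, and erythroid genes at -0.40 without genes higher in the other table. Leaving out each tumour gave, in the human table, -0.23 to 0.15 for MLL fusion targets and -0.11 to 0.31 for primitive and granule myeloid genes. In the mouse table it gave -2.52 to 1.78 for keratinocyte markers, -4.64 to 0.019 for skeletal muscle, -1.32 to 1.28 for erythroid genes, -1.29 to 0.038 for dendritic cells and MHC class II, -0.72 to 0.034 for macrophages, -0.36 to 0.48 for neutrophils and -0.055 to 1.54 for natural killer cells. Among mouse genes it gave -3.14 to 0.17 for Fap, -4.48 to 0.084 for Col12a1, -3.33 to 0.066 for Dmkn, -3.46 to 0.10 for Rps25, -1.20 to 0.072 for Ssrp1 and -1.45 to 0.34 for Supt16.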

Other observations

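The genes named in this part, the tests of explanations and the counts over splits were chosen only after the results were seen. Some further mouse genes of the interferon response were looked at outside the fixed list, and not all of them passed. Cd274, which encodes the checkpoint ligand PD-L1, was at 8.73 ± 3.80 TPM (SD, n = 2) in untreated and 109 ± 38.3 TPM in treated tumours. The T cell attractant Cxcl9 was at 8.48 ± 2.45 and 201 ± 117 TPM, and the guanylate-binding GTPases Gbp2b and Gbp5 were at 15.0 ± 4.09 and 293 ± 170 TPM and at 4.77 ± 0.191 and 120 ± 85.8 TPM. These 4 passed over all genes after median-of-ratios scaling (limma adjusted p = 0.0402, 0.0417, 0.0342 and 0.0342) and not without it (0.588, 0.277, 0.447 and 0.212); other settings are not given for them. Irf1, Ido1, Gbp8 and Gbp10 did not pass after that scaling either (limma adjusted p = 0.183, 0.527, 0.359 and 0.0649). Mouse Ifnb1, the interferon beta gene, was at 0 in both untreated tumours and at 2.67 and 2.75 TPM in the treated ones (limma adjusted p = 1.00), and Ifng was listed at 0 in all 4. In the human table IFNB1, IFNA1, IFNG and IFNL1 stayed at or under 0.24 TPM.

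In the human cells, HLA-B was at 274 ± 47.6 and 644 ± 225 TPM, HLA-E at 84.6 ± 12.5 and 230 ± 54.3 TPM, and the peptide transporter gene TAP1 at 9.55 ± 2.52 and 24.1 ± 2.48 TPM (limma adjusted p = 0.486, 0.324 and 0.383). The nuclear long noncoding RNAs MALAT1 and NEAT1 were at 928 ± 27.2 and 2385 ± 422 TPM and at 80.7 ± 19.3 and 373 ± 198 TPM, and did not pass either (0.389 and 0.239). Both treated values lay above both untreated values for each of these 5 genes. B2M, which encodes the light chain of MHC class I, was at 841, 968, 631 and 1798 TPM in untreated 1, untreated 2, CBL0137 1 and CBL0137 2.

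The rise of human interferon-stimulated genes was set against mouse RNA read as human, since the corresponding mouse list rose too. Within a treated tumour, abundant mouse matrix genes (at least 50 TPM) had a median human-to-mouse TPM ratio that was at most 0.0190 of that of the interferon-stimulated genes. This argues against such reads as the whole source only if both sets of genes are misread at a like rate, which was not measured. The ratio compares levels in the treated tumours, and the rise over the untreated ones was not tested in this way. The erythroid and stromal genes, set as a check on mouse RNA in the human table, had higher means in both treated tumours. The erythroid mean log2(TPM + 1) was 0.0101 and 0.0154 in untreated 1 and 2, and 0.393 and 0.0997 in CBL0137 1 and 2. The stromal list did not pass (camera adjusted p = 0.339). More mouse reads counted as human in the treated tumours therefore remain possible. A single unusual library does not account for the rise of the interferon list. The list's median in CBL0137 replicate 2 alone stood 1.85 above that of all genes. The 4 tumours have only 3 splits into pairs, too few for a share under 0.05: the real split, alone among them in reaching that count (1 of 3), had 13 human lists past the test and the highest other had 5. An effect of the drug on the leukaemia cells, their answer to interferon from mouse cells, or mouse reads counted as human may explain the rise. More than 1 of these may contribute, and they were not told apart. Whether interferon from mouse cells acts on these human cells was not tested.

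The lower S-phase, G2 and mitosis genes in the human table were set against a shift of scale. With small structural RNAs left out and TPM rescaled, the median log2 change of both lists together was -2.22, so scaling by those RNAs does not produce the fall. In CBL0137 replicate 2 alone, without the tumour that stood apart, it was -2.08 relative to all genes. Fewer dividing leukaemia cells, by arrest or by loss of the dividing ones, may underlie the fall, and bulk RNA does not separate these.

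Muscle, fat and skin markers may reflect how much adjacent tissue each piece of tumour held. After median-of-ratios scaling, the larger difference within a group was 2.33 times the difference between groups for muscle and 30.6 times for keratinocytes. Uneven sampling would give this, but so would any large spread within a group. For keratinocytes the difference between groups was only 0.13 in mean log2(TPM + 1). For adipocytes the ratio was 0.700, and both treated tumours lay above both untreated, so uneven sampling and an effect of treatment cannot be told apart from 2 tumours a group. Among the splits of the mouse table, again too few, the real split had 13 lists past the test and the highest other 7 (1 of 3 reached the real count). For single genes the split that sets untreated 1 and CBL0137 1 against the others called 21, more than the 14 of the real split, and keratinocyte markers were also high in those 2 tumours.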
